A study of Mus musculus with 12 samples.

How the data were processed

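RNA levels were measured on 12 Affymetrix mouse arrays, 1 per sample, in 4 groups of 3. Leukaemic stem cells came from 2 mouse leukaemias started in donor stem and progenitor cells that were either wild-type or homozygous for a gene trap in Msi2. Per the labels' protocols, total RNA was extracted with Trizol and hybridised as biotin-labelled cRNA. The deposited values are intensity values per probe set on a linear scale, made by the authors with GCRMA per the submitters' processing notes. Its version and settings were not given in the sources used here. GCRMA corrects probe brightness for background by probe sequence, normalises between arrays and summarises the probes of a probe set. A strong background correction of this kind presses dim probe sets onto a floor, here 4.49 on every array, so a change of a dim gene is only partly measured.

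Every array held 45037 probe sets, with median intensities between 13.1 and 13.8. Of these probe sets, 34945 were paired with 1 gene symbol, 932 with several and 9160 were not listed in the annotation table used, and only the first kind was named. Log2 of the intensity was taken without a pseudocount. A probe set was kept where log2 was above 4, which is 16 intensity units, on at least 3 of the 12 arrays, and each gene was represented by its probe set with the highest mean over all arrays. This left 10817 genes. For 5023 of them more than 1 probe set passed the filter. Neighbourhood on a chromosome was taken from a RefSeq gene table by gene identifier, with 34741 of the 34945 probe sets matched, and no coordinates are given because the array values carry no genome build. The number of arrays, 3 per group, limits the precision of every value.

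Group means were fitted with limma 3.58.1 in R 4.3.3 over all 12 arrays, which share 1 estimate of the spread per gene (8 residual degrees of freedom, moderated by eBayes with 2.19 prior degrees of freedom). Contrasts were the Msi2 mutant minus wild-type difference in AML, the same difference in bcCML, the mean of both (the shared effect), the bcCML difference minus the AML difference (the interaction) and wild-type bcCML minus wild-type AML. All tests were two-sided, and adjusted p values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Fold changes are log2 differences with their standard error. Where all 3 arrays of a group lay below 16 units, the ratio is written as a bound, at least so many fold, from the brighter group's mean log2 against the filter level. Where only a group's mean lay below it, the levels are given without a size, a rule added after the values were seen. The comparisons, gene lists, alternatives and rule for naming genes were fixed before the data were examined.

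Gene lists (30 with at least 5 tested members) were compared with all other tested genes by limma's camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists. Camera with an estimated correlation and limma's fry, which asks whether a list's genes move one way on balance, were alternatives. With camera at an estimated correlation no list passed in any comparison, where 2 lists in AML, 3 in bcCML, 2 in the shared effect, 3 in the interaction and 3 between the leukaemias had an unadjusted p under 0.05. Every camera call below therefore rests on the preset value. Fry, which uses no preset value but asks a different question, also called some of these lists. They were 1 in AML, 1 in the shared effect, 9 between the leukaemias and 0 in bcCML and in the interaction.

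Genes were named by this rule. Among genes past the threshold whose arrays did not overlap between the groups, the 10 largest rises and 10 largest falls were named, or the 5 smallest p values in a direction with fewer than 5 such genes. Added to these were a fixed set of genes of the leukaemias and of Msi2 biology, up to 4 members of each list with the smallest p, and genes called in the same direction in both leukaemias.

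The titles call the samples biological replicates, and correlations between replicates ran from 0.939 to 0.981. No 2 arrays had more than 14.7% identical values. Replicate numbers recur in every group. Whether they pair the arrays was checked from the correlation of deviations from the group means. In bcCML the same-numbered mutant and wild-type arrays correlated at 0.396, 0.364 and 0.278, so the numbers were treated as pairing the bcCML arrays, from the data and not from a stated design. In AML the values were -0.055, -0.121 and -0.030, and between wild-type arrays of the 2 leukaemias 0.016, 0.236 and 0.111, so these were not treated as pairs. The fit without a block stayed the planned one, and fits with the replicate number as a block were alternatives.

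The fit was tested on simulated data for the 10817 genes, with 100 genes changed by each size. At a log2 change of 1 it recovered 39% of the changed genes in AML, 44% in bcCML, 70% in the shared effect, 18% in the interaction and 46% between the leukaemias. At a log2 change of 2 these shares were 79%, 86%, 92%, 65% and 69%. In the same order, 4.1%, 3.0%, 4.1%, 8.8% and 5.7% of the calls were false, with the interaction and the leukaemia difference above 5%. The simulated noise was independent between genes and arrays, without the correlation between genes or the bcCML pairing seen in the data. The simulation also had no intensity floor and changed few genes, whereas 3996 genes passed between the leukaemias in the data. The shares are therefore not the power of the real fits. Other filters, normalisations, probe set rules, variance models, array weights, thresholds and the omission of each array in turn were tried, with their effect given in the closing section. A further 2 alternatives were added after seeing the data: a block in bcCML alone, and leaving out a pair of AML arrays that stood apart. Figures were drawn with matplotlib 3.10.9. Scan dates and batches were not given in the sources used here.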

Results

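The arrays measured RNA in leukaemic stem cells from 2 mouse models. De novo acute myelogenous leukaemia (AML) was driven by the MLL-AF9 fusion, and its stem cells were sorted as lineage-negative, Sca1-negative, Kit-positive cells. Blast crisis chronic myelogenous leukaemia (bcCML) was driven by BCR-ABL with NUP98-HOXA9, and its stem cells were lineage-negative. In each model, 3 arrays came from wild-type donor cells and 3 from donors homozygous for a gene trap in Msi2, which encodes the RNA-binding protein Musashi2. The design asks what loss of Msi2 changes in each leukaemia, and the title of the series names Tspan3, a tetraspanin membrane protein. Between 48.4% and 48.8% of probe sets lay above the filter level on each array. The first principal component, with 76.2% of the variance, parted AML from bcCML. On the second, with 4.90%, AML mutant array 1 lay at 58.2 and the other AML arrays between -20.0 and -1.20. Monocyte and macrophage genes averaged 0.96 above their mean over all arrays on that array (log2) and between 2.09 and 2.93 on the other AML arrays.

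Msi2 RNA was lower in mutant cells of both leukaemias. In AML, its brightest probe set fell from 312 ± 125 to 69.6 ± 17 intensity units (SD, n = 3), a log2 change of -2.11 ± 0.34 (SE; limma adjusted p = 0.0211). In bcCML it fell from 3827 ± 1085 to 605 ± 117 units (SD, n = 3), a log2 change of -2.63 ± 0.34 (SE; limma adjusted p = 0.0200). All 5 tested Msi2 probe sets were lower in both leukaemias, with 3 past the threshold in AML and 1 in bcCML, while 3 further probe sets stayed below the filter. Another of them went from 227 to 10.2 units in AML, below the filter level on all mutant arrays, and measured 2891 and 1292 units in bcCML, a log2 difference of -1.18 not past the threshold. Residual signal remained in mutant bcCML cells, whose Msi2 level was above that of wild-type AML. The AML call ended without AML wild-type array 1 (adjusted p = 0.0876). The bcCML call ended without AML wild-type array 1 (0.0519), bcCML wild-type array 2 (0.0729) or 3 (0.0618), or bcCML mutant array 1 (0.0737) or 3 (0.0678), with log2 changes between -2.65 and -2.48.

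Tspan3 fell in Msi2 mutant AML, from 80.5 ± 26.0 to 19.3 ± 11.7 units (SD, n = 3), a log2 change of -2.26 ± 0.46 (SE; limma adjusted p = 0.0445). In bcCML it measured 274 ± 32.8 in wild-type and 183 ± 38.3 in mutant cells (SD, n = 3), a log2 difference of -0.60 ± 0.46 that did not pass the threshold (adjusted p = 0.792), although the 3 mutant arrays lay below all 3 wild-type arrays. The test of the difference between the leukaemias gave a log2 value of 1.66 ± 0.65 and did not pass either (adjusted p = 0.456). Among the 19 tested tetraspanins, Tspan3 was the only one past the threshold in AML, and none passed in bcCML. Adjusted over the list alone, Tspan8 (365 units in wild-type, 959 in mutant cells) rose and Tspan5 (559 and 328 units) fell in bcCML. The AML call lay close to the threshold: it ended on leaving out any one of 10 of the 12 arrays, with adjusted p values from 0.0566 (without AML wild-type array 3) to 0.141 (without AML wild-type array 1), and was kept without AML mutant array 1 or 3.

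**Figure D1:**
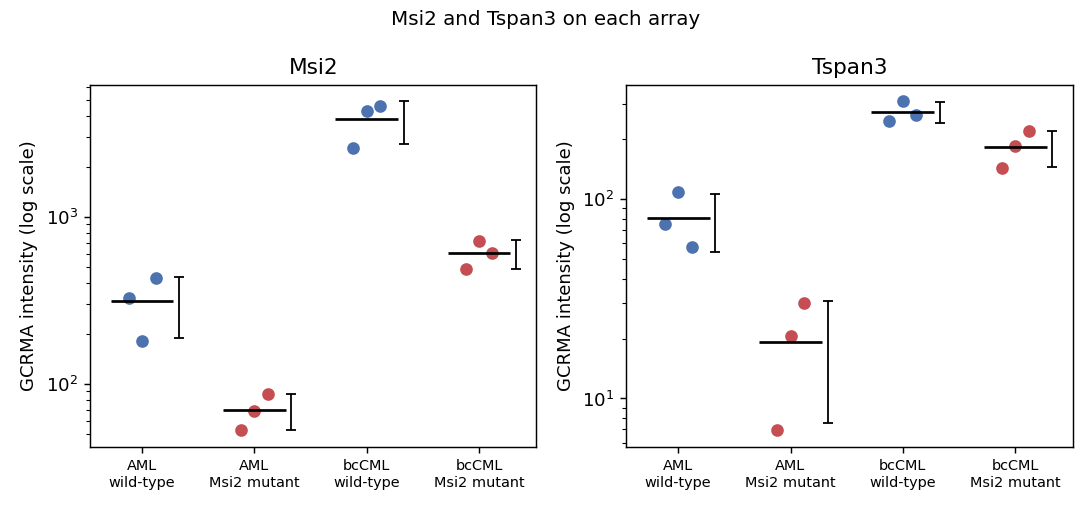
Intensity of Msi2 and Tspan3 on a log axis for each of the 12 arrays, in 4 groups of 3. Points are arrays, horizontal lines are group means and vertical bars are the SD. Mutant AML arrays lie between 52.9 and 86.9 units for Msi2 and between 6.92 and 30.3 for Tspan3, below all wild-type AML arrays.

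Loss of Msi2 in AML was accompanied by more falls than rises: 164 genes passed the threshold, 123 lower and 41 higher. Pbx3, a DNA-binding partner of Hox proteins, fell by 2.08 ± 0.25 on the log2 scale (limma adjusted p = 0.00514), and Angpt1, a ligand of the Tek receptor, fell by 3.08 ± 0.55 (adjusted p = 0.0297). Cd93, a surface protein of progenitors and myeloid cells, fell by 1.38 ± 0.27, and Ly86, a partner of the receptor Cd180, by 1.43 ± 0.27. Both calls ended without AML mutant array 1, which was low in monocyte genes (adjusted p = 0.0736 for Cd93 and 0.0548 for Ly86). Cd34 (1235 units in wild-type, 171 in mutant cells) and the receptor gene Flt3 (488 and 68.6 units) had large differences that did not pass over all genes (adjusted p = 0.0946 and 0.0926). Adjusted over the list alone, 4 of 25 stem and progenitor genes fell (Angpt1, Cd34, Flt3 and Sox4), against 1 over all genes, and the list as a whole did not pass (adjusted p = 0.774). Pbx3 was the only one of 19 Hox and Meis programme genes past the threshold in AML, and that list did not pass either (median -0.07, adjusted p = 0.774). Hoxa9, Meis1, Myc, Numb and Kit did not pass the threshold in AML.

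The largest falls in AML included Wfdc18 (223 units in wild-type, 5.16 in mutant cells, at least 8.26-fold lower) and Wfdc17 (6798 and 377 units), which encode small secreted whey acidic protein domain proteins, and both lie within the 50 nearest tested genes on either side of Msi2. The transcription factor gene Tcf24 fell by 3.80 ± 0.45 on the log2 scale, Mical3 by 3.75 ± 0.72, Akr1e1 by 3.35 ± 0.56 and the neutrophil collagenase gene Mmp8 by 3.34 ± 0.39. The nucleosome-binding protein gene Hmgn3 went from 159 to 15.7 units. Nefh, Abcc8 and 1700012B09Rik dropped below the filter level in mutant cells, at least 4.35-fold, 5.28-fold and 3.06-fold lower. Among the rises, Fam71b went from 6.82 to 194 units (at least 10.2-fold; limma adjusted p = 0.00193). Junos, Ano4, Azgp1 and Nid2 were likewise below the filter in wild-type AML and at least 3.88-fold, 4.20-fold, 3.53-fold and 2.23-fold higher in mutants. The Rac activator gene Dock1 rose by 3.03 ± 0.60, the lactoferrin gene Ltf by 2.66 ± 0.55, Sdk1 by 3.39 ± 0.62, Insyn2a by 2.72 ± 0.52 and Abcg3 by 2.55 ± 0.49. Also called were the angiogenic factor gene Vegfa (higher by 1.27 ± 0.23) and the pro-apoptotic gene Bik (at least 1.77-fold lower).

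**Figure D2:**
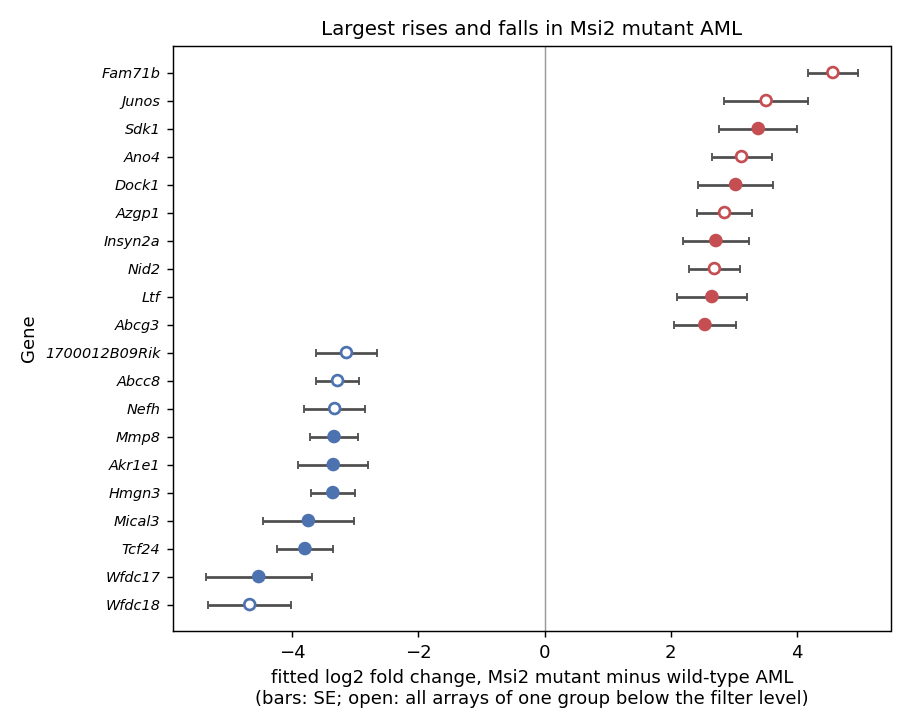
Log2 fold change, Msi2 mutant minus wild-type AML, of the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap. Points are limma estimates, bars the SE, the vertical line marks 0, and open points mark genes with all arrays of a group below the filter level, whose size rests on the floor. Among filled points, values run from -4.54 (Wfdc17) to 3.39 (Sdk1).

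A list of Myc target genes, most of them of the nucleolus and ribosome production but with genes of metabolism such as Cad, Ldha, Odc1 and Srm among them, was lower as a group in mutant AML. All 41 tested members had negative estimates, with a median of -0.44 on the log2 scale (camera adjusted p = 1.98e-12 with the preset correlation; adjusted p = 0.486 with an estimated correlation; fry adjusted p = 0.0196). Of these, 18 fell when adjusted over the list alone and 1 over all genes, Rrp12, which acts in maturation of ribosomal subunits (-1.18 ± 0.21, adjusted p = 0.0289). Nolc1 differed by -1.12 ± 0.24 and Pa2g4 by -0.62 ± 0.13, short of the threshold over all genes (adjusted p = 0.0528 for both). Oxidative phosphorylation genes had a median of -0.12 over 65 members (adjusted p = 0.00509; 0.922 as the adjusted p with an estimated correlation), with Ndufv1 of complex I lower by 0.80 ± 0.13. Branched-chain amino acid genes had a median of -0.43 over 17 members (adjusted p = 0.0127; estimated-correlation adjusted p = 0.570), and Acad8 and the transporter gene Slc7a5 fell by 1.11 ± 0.21 and 0.91 ± 0.18.

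Lists with higher medians in mutant AML were those of secondary granules (0.61, adjusted p = 0.00175; 17 of 21 members positive), primary granules (0.47, 0.0127; 13 of 18), immediate early genes (0.41, 0.00175; 23 of 28), megakaryocytes (0.58, 0.0201; 11 of 14) and TGF-beta signalling (0.18, 0.0252; 16 of 21). With an estimated correlation their adjusted p values were 0.570, 0.846, 0.570, 0.747 and 0.486. Some megakaryocyte genes lay near the floor in AML, so that list was only partly measured there. From wild-type to mutant AML, Ppbp measured 4.5 and 4.51 units, Pf4 9.43 and 4.7, and Gp1bb 6.12 and 54.9 (mutant SD 62.9, n = 3). Within the secondary granule list Ltf rose and Mmp8 fell, and no member of the other 4 lists passed over all genes. Each of these 5 calls ended without at least 1 AML array: secondary granules without wild-type array 2 (0.0512), primary granules without wild-type or mutant array 3 (highest 0.0901), immediate early genes without mutant array 2 (0.199), megakaryocytes without wild-type or mutant array 2 (highest 0.192) and TGF-beta genes without wild-type array 2, mutant array 2 or mutant array 3 (highest 0.255). Oxidative phosphorylation (highest 0.176) and branched-chain amino acid genes (highest 0.127) lost theirs without wild-type array 2, or without mutant array 3 and mutant array 1 respectively, whereas the call of nucleolar and other Myc target genes was kept in all 12 cases. The count of 164 genes became 43 without AML wild-type array 1, 104, 98 and 71 without bcCML wild-type arrays 1, 2 and 3, and 102 and 93 without bcCML mutant arrays 2 and 3. Fitted with limma on the 6 AML arrays alone it was 0, with 1207 genes at an unadjusted p under 0.05. The count of 8 lists became 4 without AML wild-type array 2.

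In bcCML fewer genes passed: 11 were lower and 4 higher in Msi2 mutants. The largest falls were Fbp1, the gluconeogenic enzyme fructose-1,6-bisphosphatase (208 to 14.2 units; limma adjusted p = 0.0185), the unconventional myosin genes Myo16 (at least 5.46-fold lower) and Myo7a (-2.56 ± 0.27), the receptor gene Mchr1 (-3.23 ± 0.49) and Fcgr3, a low-affinity receptor for IgG (2126 to 349 units, -2.59 ± 0.36). Tubd1, which encodes delta-tubulin, fell by 2.08 ± 0.32 and lies near Msi2. St6galnac3 (at least 1.45-fold lower), 1810073O08Rik (-1.60 ± 0.23) and 4930486L24Rik (-1.50 ± 0.23) fell too. The 4 rises, Cuedc1 (at least 13.6-fold; adjusted p = 0.0314), Pik3r6 (at least 3.48-fold), Cttnbp2 (at least 2.75-fold) and the pancreatic polypeptide gene Ppy (at least 1.82-fold), all started below the filter in wild-type cells, and Prkca (1.42 ± 0.24) did not pass (adjusted p = 0.0763). Cuedc1, Pik3r6, Ppy and Prkca lie on the chromosome that carries Msi2.

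Interferon response genes were higher as a group in mutant bcCML. The median was 0.82 on the log2 scale and 30 of 38 members were positive (camera adjusted p = 4.28e-09; adjusted p = 0.643 with an estimated correlation), though no single member passed. Ifi27l2a measured 55.1 and 633 units in wild-type and mutant cells and Oas3 9.11 and 70.8 units (adjusted p = 0.444 and 0.543). The p53 target list had a median of 0.30 with 16 of 20 members positive (adjusted p = 0.000597; 0.212 as the adjusted p with an estimated correlation). Adjusted over the list alone 3 of its members rose, and over all genes none, with Eda2r at 1.16 ± 0.21 and Phlda3 at 2.00 ± 0.44. Higher medians were also called for T and NK cell genes (0.57 over 9 members, adjusted p = 0.0116), mitotic genes (0.10 over 44, 0.0177) and cholesterol synthesis (0.19 over 20, 0.0250), with adjusted p values of 0.212, 0.882 and 0.7 with an estimated correlation.

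Primary granule genes, which encode neutrophil proteases and related proteins of granulocyte progenitors, had lower estimates in mutant bcCML for 15 of 18 members, with a median of -1.22 (adjusted p = 0.000597; estimated-correlation adjusted p = 0.643). The cathepsin G gene Ctsg measured 10430 and 2929 units, Elane 1352 and 315 units, and neither passed alone (adjusted p = 0.422 and 0.543). Secondary granule genes had a median of -0.34 (adjusted p = 0.0250; estimated-correlation adjusted p = 0.643), and 3 of 21 fell when adjusted over the list alone and none over all genes. Mast cell, basophil and eosinophil genes had a median of -1.27 with 8 of 10 members negative and did not pass (adjusted p = 0.0841; estimated-correlation adjusted p = 0.7). Mutant array 3 was the lowest bcCML array for both this list (-1.12 from the mean over all arrays) and primary granule genes (-2.54). Of the 7 lists, interferon and p53 genes kept their call on leaving out any array. Primary granules lost theirs without bcCML mutant array 3 (0.0620) and T and NK genes without bcCML wild-type array 2 (0.0853). Mitotic genes lost it without bcCML wild-type array 1 or mutant array 2 or 3 (highest 0.314), cholesterol genes without those or wild-type array 2 (highest 0.126), and secondary granules without AML mutant array 1, bcCML wild-type array 2 or bcCML mutant array 1 or 3 (highest 0.443).

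The numbers were treated as pairing the bcCML arrays, from correlations that chance could give, since only 6 ways to pair exist. The count was therefore also taken with the replicate number as a block. It called 27 genes in place of 15, 12 of them in common, and 42 with the block in bcCML alone, 13 in common. With the block 1810073O08Rik and 4930486L24Rik no longer passed, and all 7 lists did. Sex-linked RNA varied among the bcCML arrays: the Y-linked gene Eif2s3y lay between 2228 and 3228 units on the wild-type and between 218 and 2844 on the mutant arrays, and Xist between 15.6 and 29.1 and between 15.6 and 89.0 units, with overlapping ranges and neither past the threshold (limma adjusted p = 0.597 and 0.640). Without a block the count was 7 without AML wild-type array 1 or bcCML mutant array 1 and 8 without AML wild-type array 2 or AML mutant array 3. Fitted with limma on the 6 bcCML arrays alone it was 0, with 1042 genes at an unadjusted p under 0.05. The count of 7 lists became 4 without bcCML wild-type array 2 and 3 without bcCML mutant array 3.

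Across both leukaemias 51 genes passed for the shared effect, 40 lower and 11 higher. Msi2 and Tubd1 were the 2 genes called separately in both, each lower, where 0.125 were expected by chance (Fisher's exact p = 0.00660, two-sided; both tests use each gene's 1 estimate of spread, so they are not independent). Msi2 is the trapped gene, lower by design, and without it the overlap was Tubd1 alone, where 0.113 were expected (Fisher's exact p = 0.107, two-sided). With Msi2 included, the count was 2 without AML wild-type array 3 or bcCML wild-type array 1, and 0 or 1 without any one of the other 10 arrays. Tubd1 fell by 2.59 ± 0.32 in AML. The potassium channel subunit gene Kcne3 fell by 2.21 ± 0.33. Mocos, which encodes molybdenum cofactor sulfurase, rose by 1.20 ± 0.19, Ints2 by 0.88 ± 0.13, the kinesin gene Kif1b by 0.84 ± 0.14 and Tnip1 by 0.60 ± 0.10 (limma adjusted p between 0.0287 and 0.0367 for these 4 rises). Some others past the threshold (adjusted p between 0.00598 and 0.0438) had a group mean below the filter level of 16 units, so only their levels are given. From wild-type to mutant cells, 4933439C10Rik went from 37.8 to 5.40 units in AML and from 206 to 29.7 in bcCML, the heparan sulfate sulfotransferase gene Hs3st3b1 from 113 to 20.8 and from 135 to 11.2, and the sialic acid lyase gene Npl from 40.8 to 10.8 and from 79.5 to 47.8. Armcx1 went from 38.4 to 9.83 and from 157 to 88.5, Zbed3 from 16.5 to 4.99 and from 109 to 65.8, Cuedc1 from 6.39 to 15.8 and from 11.4 to 252, and Mfap3l from 13.7 to 27.5 and from 5.42 to 9.08 units. Tspan3 at -1.43 ± 0.33 did not pass (adjusted p = 0.0938). Across the 10817 genes the 2 genotype effects correlated weakly (Pearson r = 0.0749, Spearman rho = 0.0841; across genes, which are not independent replicates), and 107 of the 164 genes called in AML (65.2%) had the same sign in bcCML, against 54.2% of all genes.

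Lists called for the shared effect were nucleolar and other Myc target genes (median -0.26, adjusted p = 1.19e-09), oxidative phosphorylation (-0.08, 0.0242) and branched-chain amino acid genes (-0.22, 0.0137), which were lower, and interferon (0.33, 0.00348), immediate early (0.19, 0.00662), megakaryocyte (0.56, 0.0121) and p53 target genes (0.17, 0.0137), which were higher. With an estimated correlation the smallest adjusted p of any list was 0.547. Megakaryocyte members near the floor in AML limit that list here too. With the replicate block 3 genes passed in place of 51, among them Msi2 and Tubd1, and oxidative phosphorylation no longer did (0.0674). Without single arrays the Myc target call was kept, and the other 6 ended in some cases: p53 targets without AML wild-type array 2 (0.0894), immediate early genes without AML wild-type or mutant array 2 (highest 0.125), interferon genes without AML wild-type array 1 or 3 or AML mutant array 2 (highest 0.0842), megakaryocyte genes without AML wild-type array 2, bcCML wild-type array 2 or bcCML mutant array 1 (highest 0.153), branched-chain amino acid genes without AML wild-type array 2, AML mutant array 1 or bcCML wild-type array 2 (highest 0.104). Oxidative phosphorylation ended without AML wild-type array 1 or 2, AML mutant array 2 or 3, bcCML wild-type array 2 or bcCML mutant array 1 (highest 0.206). The gene count was 4 without AML wild-type array 1, 122 without AML mutant array 1, 8, 23 and 8 without bcCML wild-type arrays 1, 2 and 3, and 19 and 26 without bcCML mutant arrays 1 and 3.

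No single gene showed a difference between the 2 genotype effects that passed the threshold in the planned limma fit, which has no block. There, 1014 genes had an unadjusted p under 0.05 where 541 were expected. The smallest adjusted p values were 0.0514 for Galnt7 (-1.62 ± 0.20), Tubb2a (1.99 ± 0.27), Fam71b and Myo16, followed by values from 0.0603 to 0.0613 for Bik, Abcc8, St6galnac3, Hmgn3, Chn2 (2.62 ± 0.40) and Myo7a (-2.58 ± 0.38). Fam71b, Bik and Abcc8 lay below the filter level on average in both bcCML groups and Myo16 and St6galnac3 in both AML groups, so their genotype effect there was not measurable, and Hmgn3 in mutant AML, so no size of the difference is given for these. Among lists, primary granule genes (median -1.49, camera adjusted p = 7.02e-06) and secondary granule genes (-1.30, 1.93e-05) had a more negative genotype effect in bcCML than in AML. Interferon genes (1.05, 1.92e-05) and nucleolar and other Myc target genes (0.35, 9.48e-06) had a more positive one. With an estimated correlation their adjusted p values were 0.449, 0.447, 0.697 and 0.449. These 4 calls were kept on leaving out any array, but the interferon call ended without AML wild-type array 2 and AML mutant array 1 together (adjusted p = 0.537). The secondary granule list includes members below the filter level on average in both bcCML groups. Wild-type and mutant bcCML levels were 7.42 and 7.42 units for Mmp8, 12.9 and 15.2 for Ltf and 14.7 and 6.5 for Wfdc21. The bcCML effect of such members was barely measurable, so their difference comes mainly from AML. Genes past the threshold numbered 28 with the block in bcCML alone, added after seeing the data, and 1 with the replicate block in both leukaemias. In fits with no block they numbered 21 and 13 without AML wild-type arrays 2 and 3, and 2, 8 and 2 without AML mutant arrays 1, 2 and 3. They numbered 1 without bcCML wild-type array 2, and 5, 5 and 1 without bcCML mutant arrays 1, 2 and 3. The number of lists was 7 without AML wild-type array 1, 2 or 3, 10 without AML mutant array 1, 8 without bcCML wild-type array 3 and 9 and 8 without bcCML mutant arrays 1 and 2. On AML wild-type array 2 the interferon genes averaged 1.60 above their mean over all arrays, against -0.60 and -0.81 on the other wild-type AML arrays.

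**Figure D3:**
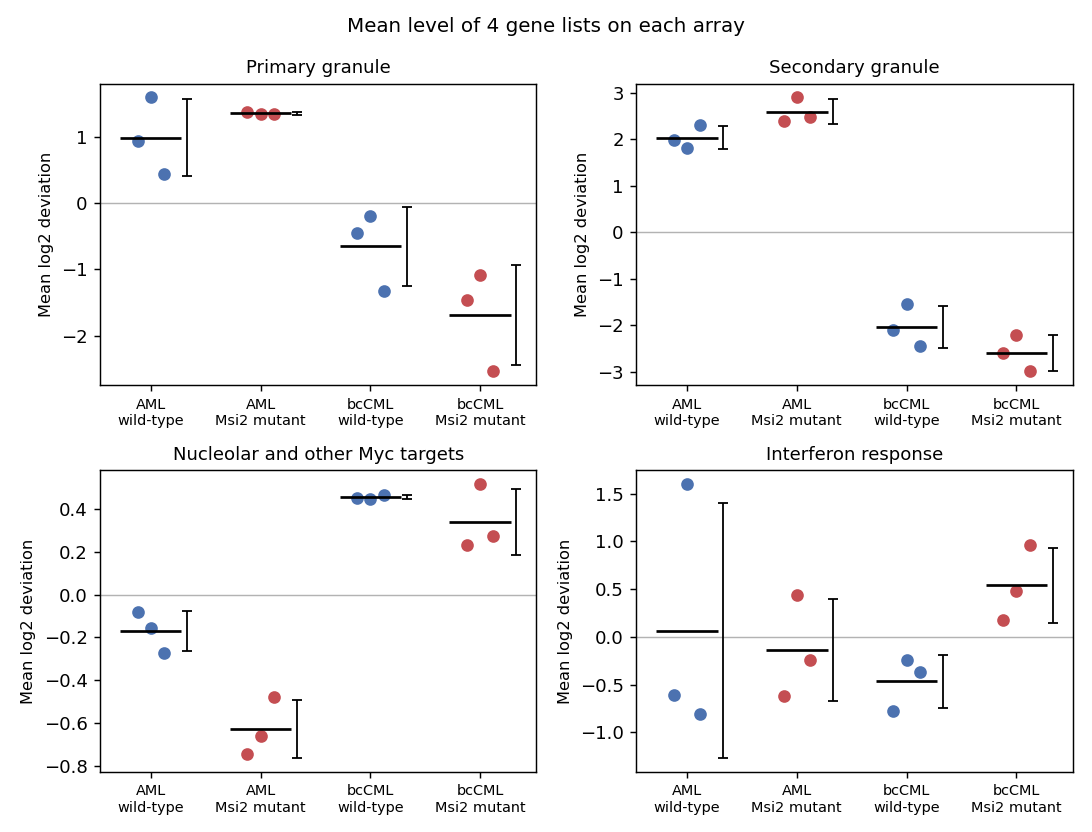
Mean log2 deviation of 4 gene lists from each gene's mean over the 12 arrays, in 4 groups of 3. Points are arrays, horizontal lines are group means and vertical bars are the SD. Primary granule genes lie between -2.54 and -1.08 on mutant bcCML arrays and between -1.32 and -0.19 on wild-type bcCML arrays.

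The wild-type leukaemias differed far more than the genotypes did: 3996 genes passed the threshold, 1913 higher in bcCML and 2083 higher in AML. Monocyte and macrophage genes were higher in AML for 24 of 28 members past the threshold, among them the receptor gene Csf1r (4016 units in AML, 4.73 in bcCML, at least 249-fold), Ms4a6c (at least 315-fold) and Ly86 (at least 194-fold). Secondary granule genes were higher in AML for 17 of 21, with the cathelicidin gene Camp at 18530 and 43.6 units and S100a9 at 31280 and 1453 units. Erythroid, megakaryocyte and mast cell genes were higher in bcCML for 14 of 20, 10 of 14 and 6 of 10 members, with Car1 (at least 339-fold), Gata1 (at least 70.8-fold), Pf4 (9.43 units in AML and 5052 in bcCML) and Ms4a2 (log2 6.37 ± 0.70) as examples. Stem and progenitor genes were higher in bcCML for 11 of 25 members and lower for 2, with Tal1 at least 90.6-fold and Hoxb5 at least 78.3-fold higher.

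Other large differences toward bcCML were Ctla2a (at least 1287-fold), Trgv4 (at least 786-fold), the thrombin receptor gene F2r (at least 719-fold), Khdc1a (at least 543-fold), Apoa1 (at least 1002-fold), Pdcd1, which encodes the receptor PD-1 (at least 192-fold), Enah (at least 229-fold) and Ablim1 (at least 161-fold). Toward AML they were the prostaglandin dehydrogenase gene Hpgd (at least 681-fold), Apoc2 (at least 248-fold), Tctex1d1 (at least 159-fold), Tifab (at least 227-fold), Sgip1 (at least 125-fold), Ctsh (2982 units in AML and 10.5 in bcCML) and Chil3 (log2 -8.28 ± 0.81). Msi2 was higher in bcCML by 3.66 ± 0.34 (limma adjusted p = 2.26e-05), Tspan3 by 1.81 ± 0.46 (0.0115) and Bcat1, a branched-chain aminotransferase, at least 72.2-fold, whereas Meis1 (-1.30 ± 0.18), Numb (-1.41 ± 0.27), Ikzf2 (-0.93 ± 0.26) and Cxcr4 (-0.81 ± 0.20) were higher in AML. Hoxa9 differed by -0.04 ± 0.15 and Kit by -0.01 ± 0.59, neither past the threshold.

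Of the 30 lists 10 passed between the leukaemias. Higher in bcCML were nucleolar and other Myc target genes (27 of 41 members; adjusted p = 5.05e-08), erythroid (5.26e-05), megakaryocyte (5.26e-05), stem and progenitor (0.00792) and mast cell genes (0.0358). Higher in AML were monocyte (5.15e-12), secondary granule (4.27e-08), adhesion (14 of 29; 0.0134), primary granule (10 of 18; 0.0358) and mitotic genes (0 of 44; 0.0358). The smallest adjusted p with an estimated correlation was 0.141. Fry, which asks only whether a list's genes move one way on balance, called 9 of these 10 lists, all but the mitotic one. Mitotic, mast cell and primary granule calls ended on leaving out 1 array: mitotic genes without AML wild-type array 1 or 2 or bcCML wild-type array 1 (highest 0.207), mast cell genes without AML wild-type array 2, AML mutant array 1 or bcCML wild-type array 1 or 2 (highest 0.118), and primary granule genes without AML wild-type array 2 or AML mutant array 1 (highest 0.0895). The mitotic call also ended with the replicate block (camera adjusted p = 0.0519). The sorts differed between the leukaemias, as did sex-linked RNA: Xist lay between 4022 and 7534 units on the 6 AML arrays and between 15.6 and 89.0 on the 6 bcCML arrays, and Eif2s3y between 5.34 and 5.77 and between 218 and 3228 units.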

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

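The tests of a single array and of mature neutrophils were chosen after the results were seen, the former because the values on leaving out arrays were already known. In 4 gene lists the test of the difference itself found unequal genotype effects in the 2 leukaemias. The bcCML effect minus the AML effect had a median log2 value of -1.492 for primary granule genes, -1.297 for secondary granule genes, 0.355 for nucleolar and other Myc target genes and 1.048 for interferon genes. All 4 rest on camera's preset correlation. In 87 of 100 splits of the arrays within each leukaemia, the real one included, at least 4 lists passed (4 in the real split, at most 13 in another), so chance cannot be excluded for the number of lists.

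Primary granule genes had lower estimates in mutant bcCML (per-array mean difference -1.04 on the log2 scale, exact permutation p = 0.200, two-sided, without regard to pairs; -1.02, -0.89 and -1.21 within the numbered pairs, exact sign-flip permutation p = 0.25, the smallest 3 pairs allow; camera adjusted p = 1.34e-07 with the block). In mutant AML they were higher by 0.36 (exact permutation p = 0.400, where 3 arrays against 3 cannot give a p below 0.1), by 0.08 without AML wild-type array 3 and by 0.67 without AML wild-type array 2. For the difference between the leukaemias, camera at the preset correlation kept its call over the 12 left-out arrays (adjusted p at most 0.000215). With an estimated correlation the list did not pass even on all arrays (camera adjusted p = 0.449). A kept call at the preset value therefore does not decide whether a single array is the cause. The size on the AML side depends on AML wild-type arrays 2 and 3, and within bcCML alone the call ended without mutant array 3. A different share of mature neutrophils, which the lineage-negative sort is meant to remove, was not excluded. Primary granule genes fell further than secondary ones in the bcCML mutants, a direction that does not speak for this cause. The primary minus secondary difference was -0.48 (exact permutation p = 0.1). Within the numbered pairs it was -0.54, -0.23 and -0.68 (exact sign-flip permutation p = 0.25). Both p values are the smallest possible, so the arrays are too few to decide. In bcCML, secondary granule genes had lower estimates for 15 of 21 members and higher ones for 6. The neutrophil gene S100a9 measured 1453 units in wild-type and 704 in mutant bcCML cells. An effect of Msi2 loss on granulocyte progenitors stays open and untested.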

How the results depend on the processing

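No gene named by the rule and past the threshold changed direction under any alternative with a single value per gene. Testing every probe set was left out of this check. There, the other tested probe set of Ints2 had a shared effect of -0.11, against 0.88 for the called one. Over the alternatives with a single value per gene, 488 of 705 values of 31 named and called genes in AML stayed past the threshold. The same held for 176 of 293 values of 13 genes in bcCML and 249 of 393 of 18 in the shared effect. Between the leukaemias it held for 2788 of 2833 values of 129 genes. Msi2 and Tspan3 in each leukaemia are given separately. The cause of the shifts below was not tested, except that fewer arrays give fewer degrees of freedom. Array weights raised the gene counts to 1053 (AML), 71 (bcCML), 750 (shared), 126 (interaction) and 6122 (leukaemia difference). Fitting only the groups compared gave 0 genes in AML and in bcCML, and Msi2 (adjusted p = 0.169 in AML at -2.11, 0.194 in bcCML at -2.63) and Tspan3 (0.272 in AML at -2.26) did not pass. Without a filter on dim probe sets, 105 genes passed in AML, 5 in the interaction, and 10 lists in the interaction, and Msi2 in bcCML (-2.63, adjusted p = 0.0656) and Tspan3 in AML (-2.26, 0.1) did not pass. A filter at log2 above 6 gave 6 genes in bcCML. The mean of a gene's probe sets gave 9 genes in bcCML and Msi2 there at -1.70 (0.194). Trend and robust moderation gave 8 genes in bcCML and 84 shared, quantile normalisation 4 in the interaction, and testing every probe set 6 probe sets in the interaction and 6511 between the leukaemias. An adjusted p under 0.01 left 23, 4, 4 and 2535 genes in AML, bcCML, shared and leukaemia comparisons, and at least 2-fold left 29 shared and 2579 between the leukaemias.

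With the replicate block the counts were 63 genes in AML, 27 in bcCML, 3 shared and 1 in the interaction, 7 lists passed in the interaction, and Tspan3 in AML did not pass (-2.26, 0.0943). No pairing by number was seen in AML, with 0 of 3 mutant arrays correlating best with their own number, against 3 of 3 in bcCML. With only 6 ways to pair, this check cannot show that the AML arrays are unpaired. With the block in bcCML alone, chosen after seeing the data, 92 genes passed in AML, 42 in bcCML and 28 in the interaction, and Tspan3 in AML had an adjusted p of 0.0898 at -2.26. Without both AML arrays that stand apart, also chosen after seeing the data, 8 genes passed in bcCML, 110 shared and 36 in the interaction, and the correlation of the 2 effects was 0.204 (0.129 with array weights).

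Lists passing with an estimated correlation were 0 in all 5 comparisons; with fry they were 1 in AML, 0 in bcCML, 1 shared, 0 in the interaction and 21 between the leukaemias. The 2 genes called in both leukaemias became 0 without a filter or with only the groups compared, 1 with the stricter filter, quantile normalisation, centring, every probe set, mean probe sets, or trend, 13 with array weights and 25 at an unadjusted p under 0.01 in both.

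Leaving out each array in turn gave 43 to 182 genes in AML, 7 to 22 in bcCML, 4 to 122 shared, 0 to 21 in the interaction and 3137 to 4351 between the leukaemias, and 4 to 10, 3 to 8, 2 to 9, 4 to 10 and 8 to 11 lists. The genes in both ranged from 0 to 2 and the correlation from 0.0173 to 0.143. Msi2 ranged from -2.46 to -1.83 in AML and from -2.90 to -2.48 in bcCML, and Tspan3 from -2.71 to -1.64 and from -0.74 to -0.43. Values near the intensity floor limit what the arrays show for dim genes.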

Other observations

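The tests of the position-free effect, of the chromosome segment, of each chromosome's correlation and of Kit were chosen after the results were seen, and the bounds of the segment and position-free tests were also changed after their values were known. Those on probe sets and sex chromosomes and the counts over other splits were set beforehand.

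Several gene groups were not called as a whole by camera in any comparison, although single members were, and fry called those named here between the leukaemias (adjusted p between 0.00163 and 0.02). Of 14 dendritic cell and MHC class II genes, 3 fell in mutant AML when adjusted over the list alone (Flt3, H2-DMa and H2-Ob), and none over all genes, with a median of -0.51 (camera adjusted p = 0.268). Among 19 tetraspanins, 8 were higher and 4 lower in wild-type bcCML than in AML, with Tspan33 at least 18-fold higher and Tspan13 higher by 5.44 ± 0.92 on the log2 scale (limma). In the Hox and Meis list, 2 of 19 were higher and 6 lower in bcCML: Bcl11a was higher by 5.09 ± 0.51, and Hoxa10 lower at -2.51 ± 0.31. RNA-binding genes of the Msi2 list had 2 of 20 higher and 4 lower, with Igf2bp3 at 2655 units in AML and 15.9 in bcCML and Lin28a at 764 and 25.7. Notch pathway members went both ways, with Notch3 at least 16.2-fold higher in bcCML and Notch1 lower at -3.61 ± 0.40, and of 15 genes 3 were higher and 5 lower.

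Between the wild-type leukaemias, 5 of 9 T and NK cell genes were higher in bcCML (Gzmb at least 104-fold) and 3 were lower (Bcl11b, Cd2 and Cd247). B cell genes were lower for 2 of 5 (Ighm at least 29.9-fold). Of 8 stromal and endothelial genes 1 was higher and 2 lower, of 40 replication genes 1 and 5, of 41 cytosolic ribosomal protein genes 3 and 0, of 22 glycolysis and hypoxia genes 5 and 2, of 29 heat shock and unfolded protein genes 3 and 2, and of 17 Bcl2 family and survival genes 4 and 5. None of these lists passed as a whole in this comparison with camera (smallest adjusted p 0.0909, for T and NK genes), whereas fry called those of T and NK cells (3.73e-06), B cells, ribosomal proteins, glycolysis and Bcl2 (adjusted p at most 0.00894).

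Genes called in the shared effect lay near Msi2 more often than elsewhere: 5 of the 100 nearest tested genes (Cuedc1, Dgke, Ints2, Mrps23 and Tubd1, of which Dgke and Mrps23 were named after their values were seen) against 45 of 10716 others, Fisher's exact p = 9.31e-05, two-sided. Over the replicate block and each left-out array this Fisher's exact p ran from 5.64e-08 to 0.0630, and was under 0.05 in 11 of 13 cases. Besides Msi2, 2 genes were called with the block and 3 without AML wild-type array 1. Without bcCML wild-type array 1 or 3, 7 were called, 1 of them near Msi2 (Fisher's exact p = 0.0630 for both). Such counts are small and neighbouring genes are not independent, so an effect of Msi2 loss without regard to position stays open. A variant under single probe sets is argued against for Cuedc1, Mrps23 and Dgke, since 6 of the 7 other tested probe sets of the called neighbours moved the same way with an unadjusted p under 0.05 (not that of Ints2, and Tubd1 had none). A chromosome segment inherited with the trap from its strain, whose name denotes a mixed background, may contribute: the 2 genotype effects correlated at r = 0.267 over the 100 genes, but 9.29% of 7973 windows on other chromosomes reached that value (a first bound of 5% was dropped, since a correlation that other windows also reach excludes nothing), so a segment and a local effect of the trap on its neighbours cannot be told apart. The correlation was not confined to them: over the 798 other tested genes of that chromosome r was 0.220, the highest of 20 chromosomes (next 0.214), against 0.0542 over all genes on others. On the whole chromosome lay 11 of 51 shared and 5 of 15 bcCML calls, where 4.24 and 1.25 were expected. The excess was smaller in AML, with 18 of 164 calls where 13.6 were expected. These counts include Msi2 itself and its 100 nearest tested genes. Among those 100 were 5 of the shared, 2 of the bcCML and 8 of the AML calls. The counts therefore do not show an excess on the rest of the chromosome.

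The wild-type leukaemias differed at 3996 genes. Genes on the X or Y chromosome made up 3.55% of the called genes and 3.12% of tested genes. Only 337 of them were tested, so they could not make up most of the calls whatever their values. This share therefore tests nothing beyond that number. Of the genes on these chromosomes 42.1% were called, against 36.8% of autosomal genes. Effects of sex on other chromosomes stay open, because all AML arrays expressed Xist and all bcCML arrays Y-linked genes. The sort on Kit could contribute: Kit differed by -0.012 on the log2 scale (95% interval -1.32 to 1.30), too wide to decide. The driver oncogenes, the sort and the donors' sex go together in the design and cannot be told apart.

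Other splits of the same arrays were counted for each comparison. For AML 164 genes passed in the real split and at most 9 in another of the 10 splits (1 split as large), for bcCML 15 and 9 (1), and between the leukaemias 3996 and 1 (1); 10 splits are too few for a share under 0.05. The 3 other bcCML splits that parted all 3 numbered pairs called at most 1 gene, and the 6 that parted 1 pair up to 9. For the lists the real and highest other counts were 8 and 9 in AML (3 splits as large), 7 and 10 in bcCML (5) and 10 and 11 between the leukaemias (5). Over 100 splits drawn within each leukaemia, 51 shared genes passed in the real split and at most 26 in another (1 split as large). This argues against chance for that count in the planned fit only. For genes called in both the real count was 2 and the highest other 1 (1 split as large). A fall of Msi2, the trapped gene, follows from the design, so that count does not test chance. Without Msi2 the count in both was 1, against 1 as the highest other (2 splits as large). Of the 100, the 36 that part all 3 numbered bcCML pairs, the real one included, gave at most 3 shared genes in another, and the splits that part fewer pairs up to 26. The shared count itself was 3 with the replicate block and 4 without AML wild-type array 1. Chance could not be excluded for the 7 shared lists (highest other 13, 52 splits) or the correlation of 0.0749 (highest other 0.267, 22 splits). The interaction, with 0 genes, was not tested by this count, since all 100 splits are then as large (highest other 26).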
